A study of Homo sapiens with 9 samples.

How the data were processed

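Total RNA of MCF7 cells was sequenced as paired-end whole-transcriptome SOLiD libraries, per the labels' protocols. The genome build was hg19, and HTSeq and DESeq2 were named, per the submitters' processing notes, without versions. The aligner, the gene annotation and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes and of close paralogs may be shared. The authors deposited 1 table for all 9 libraries. Its columns are a log2 expression value for each library, and, per the file headers, a mean signal as normalized counts (baseMean), a log2 fold change with its standard error, a Wald-type statistic (a score) and a p-value of the authors' own comparison, with no adjusted p-value. The transformation behind the deposited log2 values is not stated. They included values below 0 in 45 genes, the mean of 2 to the power of the value lay close to the deposited mean normalized count (median log2 ratio -0.0049), and libraries differed less in genes with a mean under 10 (median SD 0.091) than in genes with a mean of 10 to 100 (median SD 0.15). Such values draw low genes together, which makes their fold changes smaller than those from counts. No counts were analysed here, so the depth of each library is unknown and no counting interval is given. The deposited mean normalized counts summed to 6020955 with a median of 194 per gene.

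Samples were grouped by their titles, as 4 shNS, 2 shDDX3X hairpin 1 and 3 shDDX3X hairpin 2 libraries. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries held identical values in more than 1% of genes. The library numbers in the titles, 7 to 12 and 17 to 19, define what is called the first and the second series. Every column of values belonged to a library of the study.

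The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That design named a count test, with a linear model on log2 values as the fallback for other units. Because the deposited values are on a log2 scale, the test was limma 3.58.1 (empirical Bayes moderation with a mean-variance trend, robust, with statmod 1.5.0, in R 4.3.3) on the deposited values without a pseudocount, for genes with a deposited mean of at least 10 normalized counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fallback had foreseen a pseudocount of 1 on values that were not yet logged, and that version was run as an alternative. The comparisons were both hairpins against shNS in a model of 2 groups, and each hairpin against shNS and hairpin 1 against hairpin 2 in a model of 3 groups. Each was also fitted with the library-number series as an additive term, as planned beforehand. A model with 1 mean per series and condition, chosen after seeing the data, gave the change within each series, the difference between these changes and the difference between the series' controls. Fold changes are differences of means of deposited log2 values, with the standard errors of the fit. The DDX3X values were also compared by a two-sided exact permutation test (scipy 1.17.1).

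Gene lists were tested with limma's camera (preset correlation 0.01, adjusted over the lists of at least 5 tested genes), with camera at an estimated correlation and with fry. Fry asks whether a list's genes move, on balance, one way and does not compare the list with other genes. Of 459 genes on 20 lists, 376 were listed in the table under the same symbol and none under an older one. Named genes were DDX3X, the 10 highest and the 10 lowest fold changes of the pooled comparison among genes past the threshold, above the median mean expression of tested genes and with every knockdown library on the same side of every control, and up to 4 members of each list with the smallest adjusted p. The rule was met by 21 higher and 15 lower genes, and by 450 and 641 when applied to the fit with the series term within each series. Called members of lists with at most 6 calls in a direction with the series term were also named after their values were seen. No gene passed between the hairpins, so none is named there.

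The fits were tested on simulated data, with 200 of the 11615 genes changed by known amounts in the comparison of both hairpins against shNS. Without the series term 26.9%, 79.1% and 95.5% of genes changed by 0.3, 0.6 and 1 on the log2 scale were recovered with 0 false calls. With the term these were 71.6%, 98.5% and 100%, with 9 false calls, 4.76% of the calls. The simulation drew noise independently for each gene, chose the changed genes at random and gave them the same change in both series. In the data list members moved together and some changes differed between the series, so these rates may not carry over.

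Alternatives were no filter, a filter at a mean of 50, pseudocounts of 0.1, 1 and 5 added after undoing the logarithm, median centring, quantile normalization, equal weight for the hairpins, each library left out, each series alone and the other list tests. Genes were placed along chromosomes, and GC content and length taken from the longest transcript, in a GENCODE reference of another build than the authors', so no coordinates are given; 11706 of the listed genes were placed and 94.0% of the tested genes had a transcript. Trends with GC content and log2 length were removed with a quadratic fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.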

Results

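The study used MCF7 cells, an established oestrogen receptor-positive breast cancer cell line, carrying lentiviral short hairpin RNAs (shRNAs), which lower the RNA they match. Whole-transcriptome sequencing of total RNA gave 9 libraries. There were 4 control libraries with a non-silencing hairpin (shNS) and 5 libraries with a hairpin against DDX3X, a DEAD-box RNA helicase. Hairpin 1 was used in 2 of these and hairpin 2 in 3. The series title concerns DDX3X inhibition and the tumour cells' own type I interferon response, so the comparisons ask which genes, interferon-related ones among them, differed after knockdown. The deposited table listed 12509 genes with log2 expression values and no read counts, and 11615 genes with a mean of at least 10 normalized counts were tested. The depth of each library is therefore unknown. The deposited mean normalized counts summed to 6020955 over the listed genes.

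The library numbers in the sample titles fell into 2 runs, 7 to 12 and 17 to 19, called here the first and the second series. The first held 3 control and 3 knockdown libraries, and the second held 1 control and 2 knockdown libraries, 1 for each hairpin. No label calls these series batches. The first principal component, with 59.2% of the variance, separated the series, so each comparison is given from the design fixed beforehand, which has no term for the series, and beside it from a fit with the series as a term. Because the second series held 2 of 5 knockdown but 1 of 4 control libraries, fold changes without the term carry part of the series difference.

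DDX3X itself was lower in every knockdown library than in every control library. Its log2 expression was 11.66 ± 0.16 (SD, n = 4) in controls and 10.53 ± 0.19 (SD, n = 5) after knockdown, with control libraries between 11.56 and 11.90 and knockdown libraries between 10.26 and 10.72. The change of -1.13 ± 0.10 (SE) left 45.6% of the control level, and a two-sided exact permutation test gave p = 0.0159, the smallest these group sizes allow. Within the first series 52.9% remained, and within the second 33.7%. With the series term, hairpin 1 left 45.0% and hairpin 2 left 46.7%. The paralog DDX3Y was not analysed here.

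**Figure D1:**
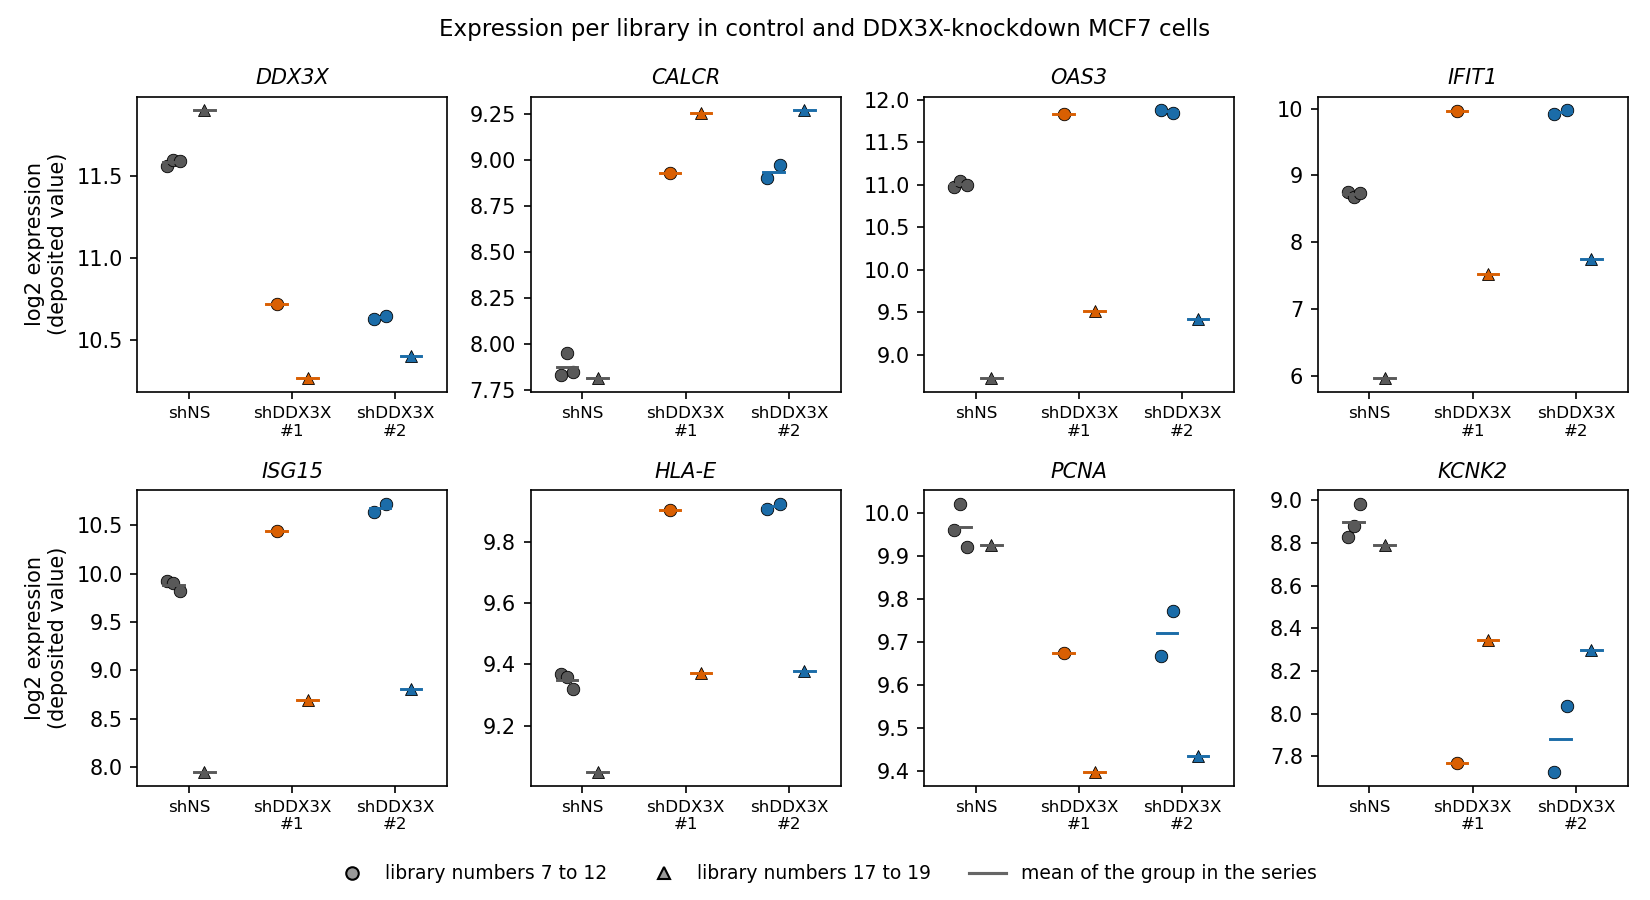
Deposited log2 expression of 8 genes in each library (vertical axes, which do not start at 0) by hairpin (horizontal axis), with circles for library numbers 7 to 12, triangles for 17 to 19 and short lines for the mean of a group within a series. DDX3X lay between 10.26 and 10.72 in the knockdown libraries and between 11.56 and 11.90 in the controls, while OAS3, IFIT1 and ISG15 were above the controls of their own series and also differed between the series.

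Interferon-stimulated genes, which encode antiviral effectors and are switched on by interferon signalling, were higher after knockdown within both series. With the series term, 42 of the 46 tested members of this list rose and none fell, with a median log2 change of 0.61. IFIT1, whose protein binds viral RNA, and IFIT3, whose protein binds that of IFIT1, rose by 1.37 ± 0.07 (SE) and 1.38 ± 0.12 (SE), OAS3, a synthase whose product activates RNase L, rose by 0.82 ± 0.04 (SE), and the ubiquitin-like protein gene ISG15 rose by 0.74 ± 0.05 (SE). In the first series ISG15 was at 9.88 ± 0.051 (SD, n = 3) in controls and 10.60 ± 0.15 (SD, n = 3) after knockdown. In the second it was at 7.95 in the lone control and 8.75 ± 0.082 (SD, n = 2) after knockdown. Every knockdown library of the first series lay above every control of that series for 45 of the 46 members. In the second series this held for 39, and over all libraries for 1. For 1 gene chance gives 5% in the first series and 33.3% in the second. Members of a list can move together, so these counts are not independent trials and do not measure chance for the list. In the fit without the term none of the 46 passed, and none did when adjusted over the list alone, although all 46 changes were positive with a median of 0.40. The set test gave adjusted p = 3.1e-51 with the term and 0.0337 with an estimated correlation. Without the term it gave 3.5e-05, lost with an estimated correlation (adjusted p = 0.735) and without shNS replicate 1 (adjusted p = 0.184). Omitting shNS replicate 1 leaves the second series, where these genes were lower, with knockdown libraries only. Without the term that omission therefore mixes the series with the knockdown. With the term, where the first series alone then informs the change, 44 of 46 were called higher.

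Genes of MHC class I antigen presentation, which display peptides to cytotoxic T cells, were also higher. In the fit with the series term 14 of 20 tested members rose, none fell and the median was 0.48. HLA-E rose by 0.49 ± 0.05 (SE), the peptide-trimming enzyme gene ERAP1 by 0.37 ± 0.06 (SE), the immunoproteasome subunit gene PSMB10 by 0.39 ± 0.08 (SE) and the peptide-editing gene TAPBPL by 0.36 ± 0.07 (SE). The set test gave adjusted p = 1.6e-19, or adjusted p = 0.0555 with an estimated correlation. Without the term no member passed over all genes, 1 did when adjusted over the list alone and the set test gave 5.7e-06, or adjusted p = 0.431 with an estimated correlation. HLA genes share sequence, so reads may be divided between them in a way that the deposited values do not show.

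Among 7 tested chemokines, cytokines and immune ligands, 3 rose with the series term. They were TNFSF10, which encodes the death ligand TRAIL, at 0.89 ± 0.10 (SE), the T cell chemokine CCL5 at 0.61 ± 0.08 (SE) and CXCL12 at 0.57 ± 0.07 (SE), while LIF was at 0.11 ± 0.08 (SE). TNFSF10 also passed without the term, with an adjusted p of 0.0490, and 2 members did so when adjusted over the list alone. The set test gave adjusted p = 0.00032 with the term, or adjusted p = 0.0604 with an estimated correlation. Without the term these were 0.0074 and 0.395.

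Of 18 tested genes for sensing double-stranded RNA and DNA, 6 rose with the series term and none fell. TRAF3, an adaptor downstream of several sensors, passed in both fits, at 0.40 ± 0.05 (SE) without the term. The RNA sensor genes DDX58 (RIG-I), IFIH1 (MDA5) and EIF2AK2 (PKR), named after their values were seen, rose by 0.60 ± 0.06 (SE), 0.53 ± 0.07 (SE) and 0.29 ± 0.04 (SE). NFKB1 rose by 0.20 ± 0.05 (SE) and DHX58, a helicase related to RIG-I, by 0.30 ± 0.09 (SE), a call lost without shNS replicate 2 and without shDDX3X_2 replicate 2 or 3, whereas RELA was at -0.05 ± 0.05 (SE). For the set this gave adjusted p = 0.00093, or adjusted p = 0.164 with an estimated correlation, and 0.29 without the term. Of 18 interferon receptor and JAK-STAT genes, 4 rose and 1 fell with the term. STAT1, STAT2 and IRF1, transcription factor genes of the interferon response named after their values were seen, rose by 0.43 ± 0.04 (SE), 0.21 ± 0.05 (SE) and 0.31 ± 0.08 (SE), JAK2 rose by 0.23 ± 0.05 (SE), and JAK1 fell by 0.13, a call lost under quantile normalization. That set test did not pass (adjusted p = 0.0958, and 0.382 without the term). No interferon ligand gene reached the filter. In the authors' deposited table the type III interferon gene IL29 had a mean of 3.45 normalized counts and a log2 change of 0.67 ± 0.19 (SE), with p = 0.0061 after Benjamini-Hochberg adjustment of the authors' p-values. In the same authors' deposited table IFNB1 had a mean of 3.90 and a change of 0.44 ± 0.19 (SE), with an adjusted p of 0.122, and IL28B had a mean of 0.11 and a change of -0.03.

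Cell cycle genes were lower after knockdown. Of the 30 tested members 22 fell with the series term, none rose and the median was -0.25. Without it 2 fell, the replication licensing gene MCM6 at -0.28 ± 0.05 (SE) and the cyclin gene CCNA2 at -0.30 ± 0.05 (SE), and 17 fell when adjusted over the list alone. The 2 calls without the term became 0 or 1 when any 1 library was left out. PCNA, the sliding clamp of DNA replication, was at -0.37 ± 0.08 (SE, adjusted p = 0.0710) without the term and fell by 0.34 with it. MCM6 was at 10.74 ± 0.054 (SD, n = 4) in controls and 10.46 ± 0.045 (SD, n = 5) after knockdown. The set test gave adjusted p = 9.1e-16 without the term and 1.5e-18 with it. With an estimated correlation these became adjusted p = 0.431 and adjusted p = 0.164.

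Replication-dependent histone transcripts, which mostly lack a poly(A) tail, moved with the cell cycle genes. Of 20 tested, 11 fell with the series term and none rose, with HIST1H3B at -0.42 ± 0.04 (SE). Without it none passed over all genes and 4 fell when adjusted over the list alone. The set test gave adjusted p = 6.3e-09 with the term and 7.8e-07 without it, and adjusted p = 0.164 and adjusted p = 0.431 with an estimated correlation. Mitochondrially encoded transcripts were higher, with 8 of 13 rising with the term, a median of 0.26 and MT-ND2 at 0.37 ± 0.07 (SE). Their set test gave adjusted p = 2.2e-07, or adjusted p = 0.164 with an estimated correlation, and 0.334 without the term. Both lists were included because such transcripts can follow RNA quality and library preparation. Their shifts accompanied the interferon and cell cycle changes in the same libraries. Whether they reflect RNA quality, preparation or, for the histones, the cell cycle was not tested.

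**Figure D2:**
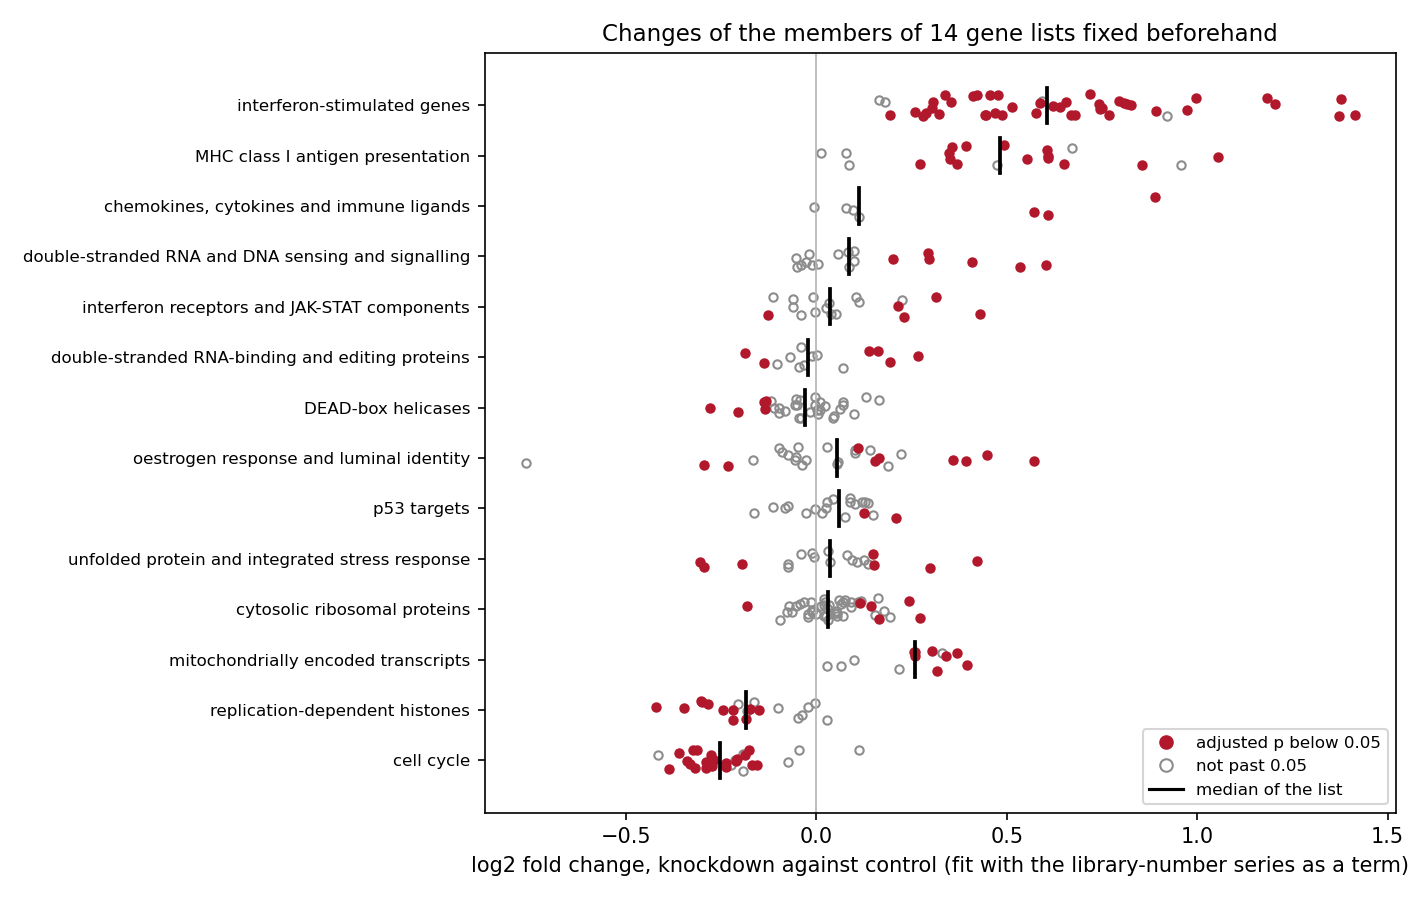
Log2 fold change, knockdown against control, of each tested member (points) of 14 gene lists (rows) in the fit with the series term, with filled points for adjusted p below 0.05 and a black bar for the median of the list. The medians were 0.61 for interferon-stimulated genes, 0.48 for MHC class I antigen presentation and -0.25 for cell cycle genes.

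Over the tested genes, 30 were higher and 20 lower after knockdown in the fit without the series term (1653 at an unadjusted p under 0.05), and 938 were higher and 979 lower with it. All 50 were among the calls with the term. When each library was centred on its median the split was 21 higher and 23 lower without the term, and 779 higher and 1257 lower with it. Without the term, leaving out any 1 library other than shNS replicate 1 gave 4 to 15 higher and 3 to 5 lower, and leaving out shNS replicate 1 gave 42 and 34.

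The genes with the highest rises in the fit without the term, by the rule fixed beforehand, were led by CALCR, the calcitonin receptor, which went from 7.86 ± 0.060 (SD, n = 4) to 9.07 ± 0.18 (SD, n = 5), a 2.3-fold change with an adjusted p of 0.00025. SYNPO2, which encodes an actin-associated protein, followed at 0.89 ± 0.13 (SE). MAN2A2, PARP6, RHOBTB3, the transcription factor gene MAFB, the interleukin receptor kinase gene IRAK1, WIPF1, the lipoprotein receptor gene VLDLR and ARNT2 rose by 0.44 to 0.60. Among the genes that fell, DDX3X led. The potassium channel gene KCNK2 was at -0.84 ± 0.13 (SE), CBX5, which encodes heterochromatin protein HP1 alpha, at -0.46 ± 0.05 (SE) and the Wnt antagonist gene DKK1 at -0.43 ± 0.05 (SE). DLGAP5, ECT2 and KIF15, which act in mitosis, were at -0.37, -0.34 and -0.32, and SLC16A14, ATAD2 and B3GALNT1 were at -0.37, -0.33 and -0.31. Of the 25 named genes called without the term, 5 stayed past the threshold in every alternative (DDX3X, CALCR, ARNT2, CBX5 and DKK1), and 20 lost the call in at least 1. The same rule applied to the fit with the series term, with separation asked for within each series, was chosen after the data had been seen. It was led on the higher side by IFIT1, CALCR, DDX60, SYNPO2, OAS3, PARP14, IFI6, MX1, ISG15 and UBE2L6. On the lower side it gave DDX3X, KCNK2, the myelin protein gene PMP22 at -0.79 ± 0.05 (SE), C14orf132, the ephrin receptor gene EPHA4, SLITRK6, AMIGO2, CBX5, BMP7 and SLC39A10.

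Of 27 oestrogen response and luminal genes, 7 rose and 2 fell with the series term. The ubiquitin ligase gene SIAH2 rose in both fits, at 0.42 ± 0.07 (SE) without the term, while XBP1 and CCND1 fell with it, by 0.30 and 0.23, and TFF3 was at -0.76 ± 0.23 (SE, adjusted p = 0.0739). As a set they gave adjusted p = 0.169 with the term and 0.993 without it, while within the second series 10 rose and 4 fell (adjusted p = 4.0e-05, or adjusted p = 0.0406 with an estimated correlation) and within the first 6 rose and 8 fell (adjusted p = 0.900). Of 32 DEAD-box helicase genes other than DDX3X, 5 fell and none rose with the term. They were DDX6, a regulator of mRNA decay, at -0.28 ± 0.03 (SE), DDX23, a spliceosome component, at -0.21 ± 0.04 (SE), DDX39A at -0.13, and DDX18 and DDX46, named after their values were seen, at -0.14 each. The calls of DDX39A, DDX18 and DDX46 were each lost without any 1 of several libraries. Their set test gave 0.106 with the term and 0.153 without. Of 14 double-stranded RNA-binding and editing genes, 4 rose, STRBP at 0.27 ± 0.05 (SE), DICER1 at 0.14 and the RNA-editing genes ADAR at 0.19 ± 0.03 (SE) and ADARB1 at 0.16, the last 2 named after their values were seen and ADARB1 lost without any 1 of 4 libraries, and 2 fell, DHX9 at -0.19 ± 0.04 (SE) and ILF2 at -0.14 ± 0.04 (SE), with adjusted p = 0.821 and 0.808 for the set with and without the term.

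Of 20 p53 target genes 2 rose with the series term, ZMAT3 at 0.21 and the cyclin-dependent kinase inhibitor gene CDKN1A at 0.12, named after their values were seen and each lost without any 1 of several libraries, and the set test gave 0.215, or 0.0945 without the term. Of 19 genes of the unfolded protein and integrated stress responses 4 rose, VLDLR at 0.42 ± 0.06 (SE), DDIT3 at 0.30, the chaperone gene HYOU1 at 0.15 ± 0.04 (SE) and EDEM1 at 0.15, and 3 fell, PHGDH and XBP1 at -0.30 each and TRIB3 at -0.20 ± 0.06 (SE). DDIT3 and PHGDH were named after their values were seen, the calls of DDIT3, EDEM1 and TRIB3 were lost when 1 of the libraries was left out, and the set test gave 0.435 and 0.289. Of 9 Wnt target genes DKK1 and CCND1 fell, and the set test gave 0.169 and 0.163. Of 10 epithelial and mesenchymal markers 3 fell, the tight junction genes CLDN3 at -0.21 and CLDN4 at -0.18 (named after its value was seen) and the splicing regulator gene ESRP2 at -0.15 ± 0.04 (SE), with CLDN3 and ESRP2 lost when 1 of the libraries was left out, and the set test gave 0.141 and 0.275. Cytosolic ribosomal protein genes had 5 rises and 1 fall among 46. RPL23 was at 0.24 ± 0.04 (SE), and RPS12 at 0.27, RPL37 at 0.17, RPL27 at 0.14, RPL30 at 0.12 and RPL7 at -0.18 were named after their values were seen, with RPL37, RPL27 and RPL30 lost when 1 of the libraries was left out. Their set test gave 0.0689 with the term and 0.0077 without it, lost with an estimated correlation (adjusted p = 0.735). Within the first series 3 ribosomal protein genes rose and 7 fell, with the set lower (adjusted p = 0.0086, or adjusted p = 0.291 with an estimated correlation), and within the second 29 rose and none fell (median 0.28, adjusted p = 4.9e-21, or adjusted p = 0.0245 with an estimated correlation). Among markers of other cell types, 1 of 5 fibroblast and endothelial genes rose, COL3A1 at 0.50 ± 0.06 (SE), and 1 of 7 basal breast genes fell, MYLK at -0.24 ± 0.08 (SE), a call lost without any 1 of 6 libraries. Their set tests gave adjusted p = 0.545 each with the term and 0.692 and 0.338 without. None of 13 haematopoietic markers was listed in the table.

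The hairpins were then compared one by one, since each is a separate reagent. With the series term, hairpin 1 raised 31 of the 46 interferon-stimulated genes and hairpin 2 raised 39, with medians of 0.62 each, and cell cycle genes fell in 20 and 19 of 30. MHC class I genes rose in 10 and 12 of 20. IFIT1 changed by 1.34 with hairpin 1 and 1.39 with hairpin 2, and CALCR by 1.19 and 1.17. The interferon set test with the term and an estimated correlation gave adjusted p = 0.0682 for hairpin 1 and 0.0658 for hairpin 2. Without the term no interferon-stimulated gene passed for either hairpin, with medians of 0.22 for hairpin 1 and 0.51 for hairpin 2. These medians also carry the series difference, because the hairpins had unequal shares of their libraries in the second series. Over all genes hairpin 1 gave 495 higher and 501 lower with the term, against 1 higher and none lower without it (1066 at an unadjusted p under 0.05). Hairpin 2 gave 628 higher and 659 lower with the term, or 517 and 887 after median centring, against 3 higher and 3 lower without it. Without the term, leaving out 1 library gave hairpin 2 counts of at most 1 higher and 1 lower, except 8 and 7 without shNS replicate 1. With the term, hairpin 1 gave 196 and 160 without shDDX3X_1 replicate 1 and 272 and 263 without shDDX3X_1 replicate 2, and hairpin 2 gave 353 to 411 and 340 to 356 without 1 of its own libraries.

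Tested directly, no gene differed between the hairpins by limma in either fit, with 525 genes at an unadjusted p under 0.05 with the term and 119 without it, where chance gives about 581. The difference for DDX3X, hairpin 1 minus hairpin 2, was -0.05 with a 95% interval of -0.51 to 0.40, and that for OAS3 was 0.02 with an interval of -0.09 to 0.12. For ISG15 it was -0.18 with an interval of -0.30 to -0.06, which excludes 0 before adjustment over all genes (adjusted p = 0.997). The controls enter this difference through the series term, and leaving out shNS replicate 1 gave 3 higher and 8 lower genes. As sets with the series term, mitochondrially encoded transcripts were higher with hairpin 1 (median 0.15, adjusted p = 1.1e-10) and histone transcripts lower (median -0.09, adjusted p = 9.9e-09), each at adjusted p = 0.356 with an estimated correlation, while interferon-stimulated genes (median -0.01, adjusted p = 0.759) and cell cycle genes (median -0.05, adjusted p = 0.0933) did not pass. Without the term the mitochondrial set was at a median of -0.03 (adjusted p = 0.900), and histone transcripts (median -0.15, adjusted p = 2.9e-06), interferon-stimulated genes (median -0.23, adjusted p = 0.0060) and cell cycle genes (median -0.08, adjusted p = 0.0031) were lower with hairpin 1, each at adjusted p = 0.946 with an estimated correlation. However, 1 of 2 hairpin 1 libraries but 1 of 3 hairpin 2 libraries belonged to the second series. Interferon-stimulated genes averaged 6.61 and 6.62 in its knockdown libraries and 8.18 to 8.19 in those of the first. The series difference therefore enters the differences without the term, which do not measure the hairpins alone.

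Within the series, the knockdown changes were compared from separate libraries on both sides. The calls share 1 estimate of each gene's spread between the series. They are therefore not independent, which can raise the number of genes called in both. Of the interferon-stimulated genes, 44 rose in the first series and 23 in the second, with medians of 0.72 and 0.31, and none fell in either. MHC class I genes rose in 17 and 7 of 20, while cell cycle genes fell in 17 and 27 of 30, with medians of -0.15 and -0.45. Over all genes 849 were higher and 883 lower in the first series, and 914 and 879 in the second, where 1 control library stands for the group and is assumed to vary like the others. Of 674 genes called in both, 625 moved the same way, 307 up and 318 down, where independent lists would share 66.8 in each direction. Across genes, which are not independent replicates, the changes in the 2 series correlated with Pearson's r = 0.412 and Spearman's rho = 0.386.

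**Figure D3:**
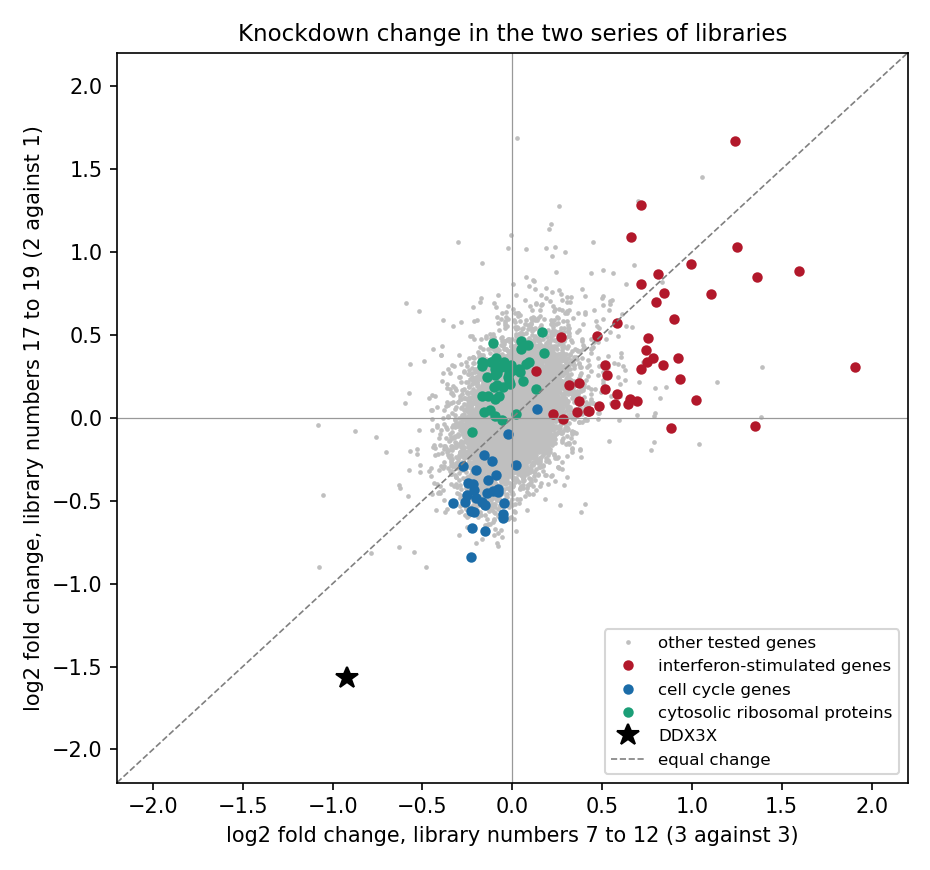
Log2 fold change, knockdown against control, in the first series (horizontal axis, 3 libraries against 3) and in the second (vertical axis, 2 against 1) for each of the 11615 tested genes, with 3 gene lists and DDX3X marked and a dashed line of equal change. Interferon-stimulated genes lay to the right (median 0.72 in the first and 0.31 in the second series), cell cycle genes below 0 on the vertical axis (median -0.45), and DDX3X at -0.92 and -1.57.

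The authors' deposited table also holds a comparison of their own, with fold changes and p-values. After Benjamini-Hochberg adjustment those p-values of the authors' deposited table gave 693 higher and 724 lower genes. Of these, 1407 were among the genes tested here, 1372 were called in the same direction with the series term and 50 without it. The authors' deposited table gave DDX3X a log2 change of -1.24 ± 0.14 (SE) and OAS3 1.02 ± 0.05 (SE). Other genes differed more from the fit with the series term. In the authors' deposited table IFIT1 was smaller, at 0.86 ± 0.22 (SE), while IFIT3, TNFSF10 and CCL5 were larger, at 1.99, 1.52 and 1.13.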

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

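The tests with GC content and length on the control libraries and on the knockdown change, the test of copy number after that trend was removed, the count of interferon-stimulated genes in the first series alone and the splits of hairpin 2 within the series were chosen only after the results were seen. The series themselves come from the library numbers.

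In 33 of 248 groups of libraries, over 124 named genes, 1 library lay farther from the rest than Dixon's 95% critical value, where chance flags about 1 in 20 groups. In 29 of these it was shNS replicate 1, the lone control of the second series. It was shNS replicate 3 in 1 group, for MAFB, and shNS replicate 4 in 1 other control group. In the controls the gap divided by the range was 0.9 for DDX3X, 0.835 for MAFB, 0.842 for AMIGO2, 0.923 for MCM6, 0.887 for DDX6, 0.836 for SIAH2, 0.897 for TFF3, 0.849 for XBP1, 0.848 for CDKN1A, 0.843 for CLDN4 and 0.925 for RPL7. Among interferon-related genes in the controls it was 0.972 for IFIT1, 0.87 for IFIT3, 0.955 for DDX60, 0.967 for OAS3, 0.974 for PARP14, 0.993 for IFI6, 0.895 for MX1, 0.951 for ISG15, 0.9 for UBE2L6, 0.973 for RELA, 0.982 for JAK1, 0.845 for HLA-E, 0.886 for CXCL12, 0.892 for IFIH1, 0.915 for DDX58, 0.865 for EIF2AK2, 0.908 for STAT1 and 0.938 for ADAR. The mitochondrial transcripts MT-ND2 and MT-ND4 had 0.854 and 0.911 in the controls. Among knockdown libraries only DICER1 (0.835) and ESRP1 (0.822) stood out, with shDDX3X_2 replicate 1 as the far library in both. The second series holds 1 control library and 2 knockdown libraries, and this measure can hardly flag 2 libraries that lie together. The contrast between controls and knockdown libraries may follow from that layout, and it does not show the knockdown libraries free of a series difference.

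The rise of interferon-stimulated genes was weighed first. An effect of 1 hairpin alone is argued against by the smaller of the hairpins' medians, 0.6203 on the log2 scale with the series term. Without the term the medians were 0.2165 for hairpin 1 and 0.5080 for hairpin 2. In that fit 1 of 2 hairpin 1 and 1 of 3 hairpin 2 libraries came from the second series, so it mixes series with hairpin. Both hairpins are compared with the same controls. Dependence on the lone second control is argued against by the first series alone, where 44 of 46 members were called. A bias with GC content and length is argued against because removing its trend left a median of 0.5971 (sign-flip permutation p = 1e-05, the smallest 100000 flips can give, over genes that are not independent). What stays open is whether the rise is biological, for which loss of DDX3X may be a candidate explanation, found and tested on the same data, with effects common to both hairpins not separated from it.

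The knockdown change differed between the series for 686 genes by the test of the difference itself. Second minus first, the log2 change differed by -0.6517 for DDX3X, 0.3947 for CALCR, 0.3848 for PARP6, 0.1907 for RHOBTB3, 0.3791 for IRAK1, 0.5845 for KCNK2 and -0.2149 for ATAD2. Among genes of the immune lists it was 0.433 for IFIT1, 0.4308 for IFI6, -0.3063 for PARP14, -0.6995 for UBE2L6, -0.2872 for RNF213, -0.7075 for IFIT3, 0.6048 for TNFSF10 and 0.4336 for CXCL12. For the others it was -0.4198 for C14orf132, 0.4967 for EPHA4, 0.3704 for BMP7, 0.3799 for STRBP, 1.04 for TFF3, 0.2157 for RPL23, 0.2348 for RPL30, 0.2431 for RPL37, 0.3515 for RPS12 and -0.348 for HIST1H2AB. The lists whose difference held with an estimated correlation had medians of -0.3294 for interferon-stimulated genes, -0.3148 for MHC class I, 0.1638 for oestrogen response, -0.2929 for cell cycle, 0.1142 for p53 targets, 0.2851 for ribosomal proteins and 0.1786 for basal markers.

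DDX3X fell further in the second series, so a deeper knockdown that scales every change was weighed. For interferon-stimulated genes the median difference was -0.3294, a smaller rise where this explanation expects a larger one. That difference rests on the 1 control library of the second series, so it does not decide. Cell cycle genes fell further in the second series, which goes with a deeper knockdown for their part. A bias with GC content and length that differs between the series is argued against because the difference hardly followed them (0.2% of its variance, Spearman's rho = 0.023 with GC content across genes), so that the same median was -0.3269 with that trend removed. A deviation of the lone second control cannot be told apart from the effect, because that series has 1 control library. A biological difference between the cells of the series also stays open as untested.

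The lone control library of the second series differed from the 3 of the first, with 1755 genes higher and 1553 lower, where that 1 library is assumed to vary like the other groups, from which the spread comes. Interferon-stimulated genes were lower there in 40 of 46 cases (median -1.04), and a GC and length trend is argued against for them by a median of -1.0569 after its removal. The series difference correlated at 0.069 between genes 10 places apart along a chromosome, above each of 1000 permuted orders (highest 0.027), which met the expectation written beforehand for a copy-number difference. It also followed GC content (Spearman's rho = -0.365 across genes), and after that trend was removed the correlation was 0.0166, within the permuted range (highest 0.0303). This later test argues against copy number and is consistent with a GC-related bias as the source of most of the neighbour correlation, without excluding a small copy-number part, while the lower interferon-stimulated genes of the second series remain unexplained by it.

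Other splits of the libraries were also counted. Without the series term, 6 of 100 drawn splits of the 9 libraries gave at least the 50 genes of the real split, so chance cannot be excluded for that count. The highest, 1538 genes, had no second-series library in its group of 5 and so followed the series. With the series term and libraries exchanged only within a series, the real split gave 1917 genes and the highest other split gave 385. That is 1 of 60 as large, the smallest share these splits can give. It argues against a random division of these libraries as the source of the count. It does not cover differences between cultures, which the labels do not describe. For hairpin 2 without the term, the real split gave 6 genes and the highest other 4, with 1 of 35 as large. These splits exchange libraries across the series, and without shNS replicate 2 no gene was called. They therefore do not settle whether chance gave that count. With the term and exchange within a series, hairpin 2 gave 1287 genes and the highest other split 1, with 1 of 20 as large, and 20 splits are too few for a share under 0.05.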

How the results depend on the processing

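The fits of each series alone, median centring, quantile normalization, a pseudocount of 1, a filter at 50 and the alternatives combined with the series term were chosen after seeing the data. The planned normalizations and count tests could not be run without counts, and no depth is known. No paired analysis was possible because the labels give no replicate numbers, and those used here only name the libraries in deposited order. A value that passed in neither setting is counted as kept.

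The series term moved the counts without it from 30 to 938 higher and 20 to 979 lower, to 42 interferon-stimulated, 14 MHC class I and 22 cell cycle genes, to 495 higher and 501 lower for hairpin 1, and to 628 and 659 for hairpin 2. The first series alone gave 898 higher, 954 lower and 44, 17 and 18 of these lists. Sharing the spread, the first series gave 849, 883, 44, 17 and 17, and the second 914, 879, 23, 7 and 27. Equal weight for the hairpins gave 9 higher, 3 lower and 0 cell cycle genes. Quantile normalization gave 0 cell cycle genes and 1 higher and 1 lower for hairpin 2. No filter and median centring each gave 1 lower gene for hairpin 1. The set test of interferon-stimulated genes without the term gave 0.7345 with an estimated correlation and 0.5398 with fry. With the term fry gave adjusted p = 0.00021 for that list, 0.0084 for cell cycle, 0.0172 for histone and 0.0218 for mitochondrial transcripts. Some lists that camera did not pass had fry at 0.00072 (DEAD-box helicases), 0.0172 (Wnt targets), 0.0300 (JAK-STAT) and 0.0402 (epithelial and mesenchymal markers). Without the term no list passed by fry, with cell cycle genes at 0.0869. Ribosomal proteins turned downward at adjusted p = 0.006073 in the first series alone, 0.008629 with the spread shared (0.291 with an estimated correlation, while in the second series 29 of 46 rose, at 0.0245 with an estimated correlation) and 0.008731 without shNS replicate 1 (with the term), and RNF213 was at -0.004368 in the second series. The downward settings for ribosomal proteins all take the change from the first series, since without shNS replicate 1 the second has no control. They are not separate support. With the term, leaving out 1 library gave that ribosomal test 0.002213 to 0.3284. The series term removes the series difference from the spread. It also removes it from the fold changes, since 2 of 5 knockdown but 1 of 4 control libraries belonged to the second series. The median of interferon-stimulated genes was 0.40 without the term and 0.61 with it. The causes of the other moves were not tested.

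Leaving out each library without the term gave 4 to 42 higher, 3 to 34 lower, 0 to 1 cell cycle genes, 0 to 2 higher and 0 to 3 lower for hairpin 1, 0 to 8 and 0 to 7 for hairpin 2, and an interferon set test of 9.025e-12 to 0.1837 (the last without shNS replicate 1). Without that library the second series keeps only knockdown libraries, so fits without the term then mix series with knockdown. With the term it gave 736 to 851 higher and 758 to 882 lower, 39 to 44 interferon-stimulated, 13 to 17 MHC class I and 17 to 23 cell cycle genes. The hairpin 1 counts with the term were 196 to 643 and 160 to 635, those of hairpin 2 353 to 765 and 340 to 789, and between hairpins 0 to 3 and 0 to 8. DDX3X stayed past the threshold in each setting, at -1.17 to -0.92 with the term. Leaving out shNS replicate 1 with the term left only the first series to inform the pooled knockdown change.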

Other observations

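The hypothesis tests on the series are given with the results looked at more closely. The lone control library of the second series differed from the 3 of the first in several gene groups, with its spread taken from the other groups. Second minus first series, IFI6 differed by -3.71 ± 0.06 (SE) on the log2 scale, IFIT1 by -2.76 ± 0.09 (SE) and OAS3 by -2.28 ± 0.06 (SE). Mitochondrially encoded transcripts were lower in 10 of 13 cases (median -0.98), oestrogen response genes were lower in 18 of 27 and higher in 3, and p53 target genes were higher in 10 of 20 and lower in 1. RNF213 differed by only -0.00 ± 0.05 (SE). The interferon-stimulated genes averaged 6.61 and 6.62 in the second series' knockdown libraries, below the 7.43 to 7.45 of the first series' controls.

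Explanations for the lower cell cycle genes were also looked at. Loss of transcripts without a poly(A) tail was looked at after the result was seen. It acts on no transcript with a tail, and the 22 of 30 members called lower with the series term are taken to carry one. By definition it cannot lower such transcripts, so this count is no test of it, and the histone transcripts stay open. Dependence on the lone second control is argued against by the first series alone, where 18 of 30 were called lower. The expectation was written before this result, although the fit itself was chosen after other results had been seen.

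After removal of the GC and length trend from the knockdown change, cell cycle genes kept a median of -0.26 (before, -0.25) and MHC class I genes 0.46 (before, 0.48). The knockdown change itself followed GC content weakly, with Spearman's rho = 0.162 across genes, and the trend took 2.9% of its variance.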
